A study of Gallus gallus with 12 samples.

How the data were processed

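Pineal glands of male chicks were profiled on an Affymetrix chicken expression array, 12 arrays in 6 groups of 2, with dark and light groups at CT6, CT14 and CT22. Per the labels, each array was hybridised with a separate biological sample, made from 9 micrograms of total RNA pooled from 6 glands and labelled with the one-cycle kit. The authors deposited 1 linear intensity value per probe set and array. The software that made these summary values, its scaling and its version are not given in the sources used here. The deposited intensities had array medians from 20.1 to 28.9, and 6.24% of all values lay under 1. Groups were taken from the sample labels. No genome was used here, so no coordinates are given.

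The table held 38535 probe sets, of which 96 were controls and were left out. Genes were named through the platform annotation supplied with the series. It gave 1 gene for 27168 of the 38439 other probe sets, several for 177 and none for 11094. No gene was named from a probe set with several, and a probe set without a listed gene counts as unnamed here. Current symbols were looked up by gene ID, and 315 probe sets had an ID that the reference table did not hold. Values were taken to log2 without a floor at that step. A rule fixed beforehand kept the deposited scale only where array medians lay within 0.2 on the log2 scale. They did not, so the arrays were quantile normalized. Normalized values under 1 on the linear scale were then set to 1. Quantile normalization gives every array the same distribution, so a change shared by most probe sets cannot be seen. Probe sets with a mean above the 40th percentile (log2 3.73) were tested, 23063 in all, 18168 of them naming 1 gene, for 10406 genes. For a gene with several tested probe sets (4921 genes) the one with the highest mean over all arrays stands for it.

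Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 6 group means over the 12 arrays, 6 residual degrees of freedom, and a moderated test with a variance trend (prior degrees of freedom 7.28). Standard errors are those of this fit and share their spread over all groups. Contrasts were light minus dark at each time, their average, the differences of the light effect between times, and the differences between dark groups. Time dependence and time of day in the dark used moderated F tests. P-values were adjusted with the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Gene lists, 22 with 509 distinct genes of which 389 were tested, were fixed before the data were examined and compared with all other genes with camera at a preset inter-gene correlation of 0.01. Where a listed symbol was missing from the array annotation, a gene holding it as a synonym took its place. A few such matches were set or left out by hand. The lists were adjusted over 88 tests for the light contrasts and 66 for the differences. Camera was run again with an estimated correlation. A further 66 tests on the dark contrasts were chosen after the data were seen.

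The lists were sterol synthesis and uptake, fatty acid synthesis, ER chaperones and the unfolded protein response, ATF4 stress targets, cytosolic heat shock proteins, immediate early genes, the circadian clock, melatonin synthesis, phototransduction, glucocorticoid targets, glycolysis and the hypoxia response, cytosolic ribosome, oxidative phosphorylation, and markers of erythrocytes, lymphocytes, macrophages, fibroblasts and meninges, endothelium and mural cells, neurons, glia, choroid plexus and ependyma, and skeletal muscle. Named genes followed a rule fixed beforehand. It took, per light contrast, the 12 largest increases and 8 largest decreases among genes past the threshold whose light and dark arrays did not overlap. Chance alone separates groups of 2 and 2 in 33.3% of cases. It added the 10 leading genes for time dependence, the 10 with the widest range between dark times, and members of the lists, and it passed over genes without a symbol. The first 3 parts named 58 genes. For these, 42 further probe sets were tested at the times concerned. Of them 35 had the same direction, 15 also passed, and 0 passed in the opposite direction.

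The fit was tested on simulated data for the CT14 contrast over 23063 probe sets, with 200 changed probe sets planted. It recovered 13 of 67 at a log2 change of 0.58, 29 of 67 at 1 and 57 of 66 at 2, with 5 false calls. At CT6, with nothing planted, it made 0 calls. Small changes are therefore mostly missed with 2 arrays per group. A list shifted by 0.5 at CT22 was recovered (camera adjusted p = 4.08e-27), and 0 other list tests passed. The simulated noise was independent between probe sets, while estimated correlations within the real lists reached 0.57, for lymphocyte markers. The simulation therefore says little of false calls among genes that vary together. Alternatives tried were the values as deposited, arrays centred on their median, no filter or a filter at the 60th percentile, a constant added before log2, other variance models, array weights, the replicate number as a block, fits of 1 time alone, each array left out in turn and, for lists, fry, an estimated correlation and the mean over probe sets. The actin ratio as a covariate was added after the data were seen. The robust variance trend, a further alternative, used statmod 1.5.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.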

Results

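Gene expression was measured in the pineal gland of male chicks with 12 Affymetrix arrays, 1 per sample. The pineal gland is a light-sensitive gland of the bird brain that makes melatonin and holds its own circadian clock. Chicks 8 days old had lived for 7 days with 12 h of light per day, followed by a day of constant darkness. They then received a 1 h light pulse starting at circadian time (CT) 6, in the subjective day, at CT14, early in the subjective night, or at CT22, late in it. Controls stayed in the dark. Glands were taken when the pulse ended, and each sample pooled RNA of 6 glands. The 3 times and 2 treatments made 6 groups of 2 arrays each, so the number of arrays limits the precision. The design question is whether the response to light depends on the time of day. Median intensity per array lay between 20.1 and 28.9 as deposited. Replicate arrays correlated with r from 0.964 to 0.975 across probe sets. The lowest of these values belonged to the 2 CT14 dark arrays. Values below are log2 changes of light over dark, with the standard error (SE) of the limma fit and its Benjamini-Hochberg adjusted p.

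At CT6, light raised a small set of genes, led by RAD54L2, which encodes a helicase-like protein, by 2.41 ± 0.17 (SE, adjusted p = 2.67e-05). LONRF3 rose by 1.90 ± 0.22 and LONRF1 by 1.75 ± 0.17, both genes of RING-finger proteins. NFIL3, a repressor of clock output genes, rose by 1.43 ± 0.11, and LSG1, a GTPase of ribosome assembly, by 1.42 ± 0.10. CHAC1, a glutathione-degrading enzyme of the ATF4 stress response, rose by 2.00 ± 0.29 (adjusted p = 0.0142). HMGCS1, an early enzyme of cholesterol synthesis, rose by 1.06 ± 0.09 (adjusted p = 8.59e-05). CCSAP, MACIR, TRNT1, ORAOV1 and MELTF completed the 12 leading increases, with changes between 0.89 and 1.49. In the other direction, LRCH3 fell by 1.15 on the log2 scale, MEF2D by 0.70, the kinase gene SIK1 by 0.60, COL18A1 by 0.54, AKAP9 by 0.47 and FRMD4B by 0.41. In all, 51 probe sets passed the adjusted threshold, 41 higher and 10 lower, and they covered 34 genes. The values as deposited gave 26 probe sets (25 higher, 1 lower), and arrays centred on their median gave 250 (243 higher, 7 lower). Without the second CT6 light array 23 probe sets passed. Of 28 calls at CT6 for named genes and list members, those of SIK1, FRMD4B, COL18A1, AKAP9 and HSPA5 were lost under more than 0.5 of the alternatives tried. A further probe set of RAD54L2 gave -0.57 at CT6 and did not pass, and those of LSG1 (2), TRNT1 (1), ORAOV1 (2 of 4) and LRCH3 (1 of 2) also had the opposite sign without passing.

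Sterol and heat shock genes rose at CT6. Of 24 measured genes of sterol synthesis and uptake, 5 rose and none fell, HMGCS1, INSIG1, FDFT1, NSDHL and STARD4, with a list median of 0.23 (camera adjusted p = 4.32e-07, and adjusted p = 0.0435 with an estimated correlation). Adjusted over the list alone, 7 rose. Among 29 cytosolic heat shock genes, 4 rose, HSPA2, HSP90AA1, DNAJA4 and BAG3, and 14 rose when adjusted over the list alone. Their median was 0.21 (adjusted p = 8.47e-12, and adjusted p = 0.0202 with an estimated correlation). The lists of sterol synthesis, fatty acid synthesis, chaperones of the endoplasmic reticulum (ER) and heat shock were chosen knowing that a published study of this tissue discusses these themes, so their calls at each time are not independent evidence. The clock list passed too (median 0.15, adjusted p = 0.0118), with NFIL3 as its 1 member past the threshold and 4 adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.143). All 13 macrophage marker genes lay higher (median 0.26, adjusted p = 0.00644), but in the limma fit 0 passed after adjustment, adjusted over the list alone included, against 4 at an unadjusted p under 0.05. That list gave adjusted p = 0.387 with an estimated correlation. HSPA5, an ER chaperone gene, rose by 0.39 ± 0.07, while the list of ER chaperones did not pass (adjusted p = 0.233).

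At CT14, early in the subjective night, light raised LONRF3, RAD54L2 and LSG1 again, along with genes such as SLC4A7 and BMP2. LONRF3 rose by 3.08 ± 0.22, RAD54L2 by 2.87 ± 0.17 and LSG1 by 2.34 ± 0.10 (adjusted p = 7.38e-08). Further probe sets did not pass: that of RAD54L2 gave 1.21, and the lower of 2 for LSG1 gave 0.06. SLC4A7, a sodium bicarbonate cotransporter, rose by 1.72 ± 0.07 (adjusted p = 2.32e-08), and the growth factor gene BMP2 by 1.85 ± 0.11 (adjusted p = 6.80e-07). RADIL, CCSAP, RASL11A, CRYBA1, INSYN1, MACIR and LONRF1 rose by between 1.64 and 2.85. RADIL, RASL11A and CRYBA1 had dark means of 3.13, 3.30 and 2.79, under the log2 limit of 3.73 that was set for the mean over all arrays. No detection calls were used here, so the size of these changes is uncertain. The CT14 dark arrays differed widely for RADIL (SD 1.06) and CRYBA1 (SD 1.20). Without the first dark array RADIL gave 3.60 and CRYBA1 2.71, and without the second 2.10 and 1.01. CRYBA1 lost its call in 14 of 23 alternatives. DIO3, which inactivates thyroid hormone, fell by 2.98 on the log2 scale (adjusted p = 4.80e-05). SLCO1C1, a thyroid hormone transporter, fell by 1.69, G0S2, an inhibitor of lipolysis, by 1.85 and the neurotrophin gene BDNF by 1.46. FAM131B, TMEM27, NXNL2 and SLC2A12 completed the 8 leading decreases. FAM131B, at -2.33, had a light mean of 2.07, also under that limit. It gave -3.09 without the first CT14 dark array and -1.57, no longer past the threshold, without the second. The count was 386 probe sets, 264 higher and 122 lower, covering 217 genes. The values as deposited gave 301 higher and 54 lower.

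The RNA of the CT14 groups differed in a quality measure. The ratio of actin signal at the 3-prime end to that at the 5-prime end was 4.67 and 3.95 in the CT14 dark arrays and 3.28 and 3.09 in the CT14 light arrays. The other 8 arrays lay between 3.62 and 4.23. With this ratio as a covariate, an alternative added after the data were seen, 23 probe sets passed at CT14, all of them higher, and 59 at CT6. The median SE of the CT14 response over all probe sets grew from 0.20 to 0.38 in that fit. Among the 264 probe sets raised at CT14 it was 0.23 in that fit, and 19 of them still passed. Of 57 named light calls at CT14, all kept their direction and 12 stayed past the threshold: LONRF3, RAD54L2, LSG1, BMP2, SLC4A7, MACIR, HMGCS1, INSIG1, HSPA2, NFIL3, CXCR4 and COL1A1. In that fit the linear fold change of 5 genes moved by over 1.5 times and their call was lost. Their log2 changes became -1.92 for DIO3, 0.59 for PER2, 3.67 for RADIL, 3.35 for CRYBA1 and -3.56 for FAM131B. With 1 array of this time left out fewer probe sets passed, with the smallest drop for the second dark array. The median light effect of the 264 raised probe sets was 0.79 with all arrays. It was 0.76 without dark replicate 1, 0.80 without dark replicate 2, 0.82 without light replicate 1 and 0.75 without light replicate 2. The 264 were chosen because they passed with all of these arrays, so this narrow range is no evidence of stability.

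Among 21 measured clock genes, 5 rose at CT14 and none fell. BHLHE40 rose by 1.61 ± 0.17, BHLHE41 by 1.12 ± 0.10, NFIL3 by 1.38 ± 0.11, CRY2 by 0.45 ± 0.09 and PER2 by 1.33 ± 0.25 (adjusted p = 0.0153). The call of PER2 was lost in 7 of 24 alternatives, among them those without the first CT14 dark array or either CT14 light array, with values from 0.59 to 1.77 over all 24. Adjusted over the list alone, 8 rose and 1 fell. The list median was 0.27 (adjusted p = 1.43e-05, and adjusted p = 0.0365 with an estimated correlation). PER1 was not analysed here. Of the sterol genes, 9 rose, among them HMGCS1 by 1.37 ± 0.09, INSIG1, a brake on sterol synthesis, by 1.35 ± 0.10, FDFT1 by 1.12 ± 0.10 and SQLE by 0.88 ± 0.11. The sterol list gave adjusted p = 2.87e-08, and adjusted p = 0.0365 with an estimated correlation, with 11 genes up and 1 down adjusted over the list alone. Of the heat shock genes, 12 rose, or 15 adjusted over the list alone (median 0.36, adjusted p = 1.50e-15, and adjusted p = 0.0124 with an estimated correlation). HSPA2 led them with 1.27 ± 0.08, followed by BAG3 with 1.16 ± 0.11.

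With the actin ratio as a covariate the sterol, heat shock and clock lists still passed at CT14. The 5 lists that follow passed with the preset correlation, and each lost its call with an estimated correlation and with the actin covariate. Immediate early genes, which commonly answer stimuli within an hour, lay lower (median -0.22, adjusted p = 0.0180, and adjusted p = 0.165 with an estimated correlation). EGR1 fell by 0.83, SIK1 by 0.78 and TIPARP by 0.53, and 2 rose and 7 fell adjusted over the list alone. FOS was not analysed here. Of 16 fatty acid synthesis genes 13 lay higher (median 0.21, adjusted p = 0.0319, and adjusted p = 0.165 with an estimated correlation). In the limma fit 0 of them passed, adjusted over the list alone included, against 3 higher and 1 lower at an unadjusted p under 0.05. The melatonin synthesis list had a median of 0.15 (adjusted p = 0.0228, and adjusted p = 0.196 with an estimated correlation). Its 1 member past the threshold was ADCY1, an adenylyl cyclase whose call was lost under more than 0.5 of the alternatives, with 2 adjusted over the list alone. In the phototransduction list RBP3, a retinoid carrier, rose by 1.17 ± 0.20 (list median 0.19, adjusted p = 0.0422, and adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone, 5 of its genes rose. Of 25 oxidative phosphorylation genes 21 lay lower (median -0.09, adjusted p = 0.0331, and adjusted p = 0.637 with an estimated correlation), and in the limma fit 0 passed, adjusted over the list alone included, against 5 lower and 1 higher at an unadjusted p under 0.05. The ER chaperone list did not pass (adjusted p = 0.0892), although HSPA5 rose by 0.88 ± 0.07, HERPUD1 by 0.67 ± 0.12 and HSP90B1 by 0.39 ± 0.07. Adjusted over the list alone, 4 of its genes rose.

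At CT22, late in the subjective night, heat shock genes held the leading increases. HSPB9, a small heat shock protein gene, rose by 5.21 ± 0.13 (adjusted p = 6.86e-11), a 37.1-fold change. HSPH1, an HSP110 chaperone, rose by 3.34 ± 0.33, HSPB8 by 2.69 ± 0.32, the co-chaperone BAG3 by 2.60 ± 0.11 and HSPA2 by 2.11 ± 0.08. HERPUD1, a gene of protein degradation at the ER, rose by 1.88 ± 0.12. RNF25, RAD54L2, LONRF3, GNG11, STEAP4 and P4HA2 completed the 12 leading increases. DUSP8, a phosphatase gene, fell by 2.24 on the log2 scale, PDCL2 by 2.27, EPSTI1 by 1.81, MCM9 by 1.56, ANKRD31 by 1.55, the early response gene EGR1 by 1.46, PAPPA by 1.42 and IL22RA1 by 1.40. Group means under the log2 limit of 3.73 were found for RNF25 and STEAP4 in the dark (2.58 and 3.19) and for PDCL2, DUSP8, EPSTI1 and ANKRD31 in light (2.34, 3.08, 2.33 and 3.43), so the size of these changes is uncertain. The calls of PDCL2 and EPSTI1 were lost under more than 0.5 of the alternatives, and PDCL2 gave -1.53, no longer past the threshold, without the second CT22 light array. The count was 840 probe sets, 398 higher and 442 lower, covering 493 genes. The values as deposited gave 166 higher and 343 lower. Without the first dark array of CT22 the count was 234, without the second 337, and without the second light array 307.

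Of the 29 heat shock genes, 19 rose at CT22 and none fell. Adjusted over the list alone, 21 rose and 1 fell. Their median was 0.62 (adjusted p = 8.40e-28, and adjusted p = 0.00358 with an estimated correlation). Of 32 measured genes of ER chaperones and the unfolded protein response, 8 rose: HERPUD1, HSPA5, SDF2L1, CRELD2, DNAJB9, PDIA6, HSP90B1 and CANX. HSPA5, the main chaperone of the ER, rose by 1.19 ± 0.07. The list median was 0.13, with 13 genes up and 1 down adjusted over the list alone (adjusted p = 8.77e-07, and adjusted p = 0.140 with an estimated correlation). Of the sterol genes, 9 rose, led by HMGCS1 with 1.58 ± 0.09, INSIG1 with 1.35 ± 0.10 and FDFT1 with 1.32 ± 0.10. That list gave adjusted p = 9.70e-08, and adjusted p = 0.0385 with an estimated correlation, with 11 genes up and 1 down adjusted over the list alone.

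**Figure D1:**
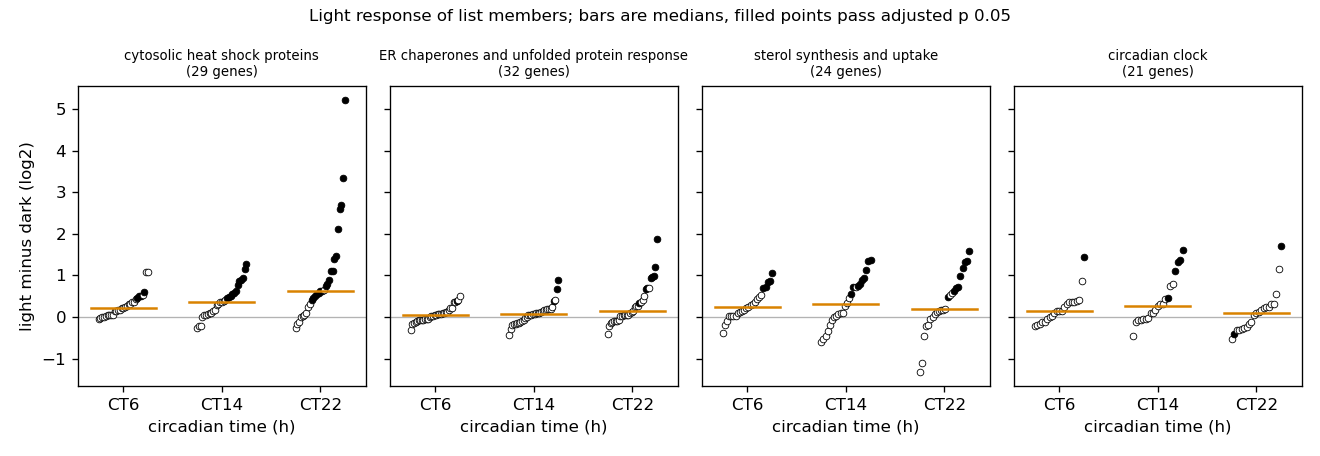
Log2 change of light over dark for each measured gene of 4 lists, by circadian time in hours; each point is a gene (1 probe set), filled where it passed adjusted p 0.05, and bars are list medians. The heat shock median was 0.21 at CT6, 0.36 at CT14 and 0.62 at CT22, while the sterol median was 0.23, 0.30 and 0.19.

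Melatonin synthesis genes included 2 that fell at CT22. AANAT, the rhythmic enzyme of melatonin synthesis, fell by 0.83 on the log2 scale (adjusted p = 5.56e-04), and DDC fell by 0.49. The list of 11 genes did not pass (median -0.10, adjusted p = 0.142), with 3 lower adjusted over the list alone. Of the clock genes, NFIL3 rose by 1.70 ± 0.11 and HLF fell by 0.42, and the clock list did not pass (adjusted p = 0.776). The call of HLF was lost in 11 of 24 alternatives, among them the values as deposited and arrays centred on their median. PDC and PDE6G of the phototransduction list fell by 0.44 and 0.25, with the call of PDE6G lost in 10 of 24 alternatives. Choroid plexus markers lay higher at CT22 (median 0.31, 7 measured, adjusted p = 0.0174, and adjusted p = 0.470 with an estimated correlation). FOLR1 and KL rose by 0.81 ± 0.17 and 0.79 ± 0.19, and 3 rose adjusted over the list alone. The call of KL was lost in 11 of 24 alternatives. The other 11 lists passed at none of the 3 times, with adjusted p between 0.0628 and 0.997. They were ATF4 targets, glucocorticoid targets, glycolysis and hypoxia, cytosolic ribosome, and markers of erythrocytes, lymphocytes, fibroblasts and meninges, endothelium and mural cells, neurons, glia and skeletal muscle. Over the 66 tests of a list at a time, 16 passed with the preset correlation, 14 higher and 2 lower, and 7 of these held with an estimated correlation: sterol and heat shock at all 3 times and clock at CT14.

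Some genes rose at every time. Of the probe sets raised at CT6, 35 were also raised at CT14, where independent lists of these sizes would share 0.469. CT6 and CT22 shared 29 (0.708 for independent lists), and CT14 and CT22 shared 81 (4.56). The dark arrays differed between times, so these overlaps share no control. They do share 1 estimate of spread per probe set, and some genes, such as LONRF1 and MACIR, enter with several probe sets. The values for independent lists may therefore be too low. Raised at all 3 times were 27 probe sets for 20 genes. They included NFIL3, RAD54L2, LONRF1, LONRF3, LSG1, the sterol genes HMGCS1, INSIG1, FDFT1, NSDHL and STARD4, and the chaperone genes HSPA2, HSPA5, HSP90AA1, DNAJA1, DNAJA4 and BAG3. Any probe set of a gene could count here. For DNAJA1 it was a further probe set, as the one that stands for the gene did not pass at CT6. SIK1 and FRMD4B were lowered at all 3 times. At CT6 the call was lost in 17 of 24 alternatives for SIK1, 19 of 24 for FRMD4B and 16 of 24 for HSPA5. Averaged over the 3 times, 691 probe sets passed, 410 higher and 281 lower, covering 393 genes. The values as deposited gave 300 higher and 104 lower, and arrays centred on their median gave 594 higher and 186 lower. With the actin ratio as a covariate 246 passed.

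The light response itself differed between times for 311 probe sets covering 189 genes in the moderated F test. HSPB9 had the lowest adjusted p among the named genes, with an effect larger by 5.08 ± 0.18 at CT22 than at CT6 (adjusted p of the F test = 8.59e-09). HSPA2, BAG3 and HERPUD1 also responded more at CT22 than at CT6, by 1.64 ± 0.11, 1.98 ± 0.15 and 1.52 ± 0.16. SLC4A7 responded more at CT14 than at CT6, by 1.43 ± 0.09. CPLX4, a synaptic complexin, rose at CT6 and CT14, by 0.71 ± 0.08 and 1.52 ± 0.08, and its change at CT22 was -0.03 ± 0.08. BMP2, BHLHE41 and MACIR responded less at CT22 than at CT14, by -1.54 ± 0.15, -1.38 ± 0.14 and -1.21 ± 0.13. For SLCO1C1 the sign turned, from a fall of 1.69 at CT14 to a rise of 0.68 ± 0.16 at CT22. For PER2, called at CT14, the difference between times did not pass (adjusted p = 0.251). The difference of AANAT passed (adjusted p = 0.0144). The heat shock list rose more at CT22 than at CT6 (median difference 0.39, adjusted p = 7.02e-17, and adjusted p = 0.0211 with an estimated correlation). The count fell to 88 with the actin ratio as a covariate and to 11 without a variance trend. Leaving out a single array gave between 73 (second CT22 light array) and 375.

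**Figure D2:**
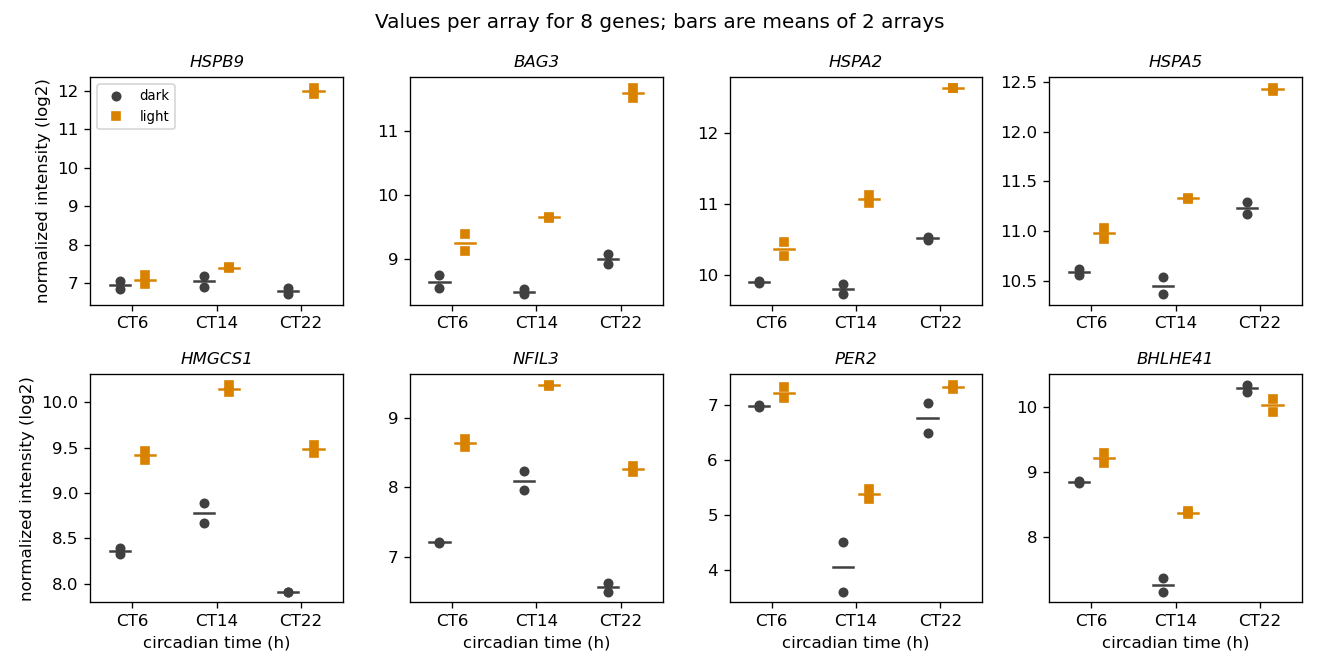
Normalized log2 intensity of 8 genes in each of the 12 arrays against circadian time in hours; circles are dark and squares light arrays, and bars are means of 2 arrays. HSPB9 rose by 5.21 at CT22, against 0.14 and 0.36 at CT6 and CT14, which did not pass the test, while NFIL3 rose at all 3 times.

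Time of day in the dark was tested with the 6 control arrays in the same fit. Clock genes changed with time. PER2 was lower at CT14 than at CT6, with a change of -2.93 ± 0.25, and PER3 changed by -2.02 ± 0.34. The range of PER3 between dark times, 3.62, was 2.83 without the first CT14 dark array and 4.42 without the second, and the CT14 change of CRYBA1, -2.73, was -3.58 and -1.88. BHLHE41 changed by -1.59 ± 0.10 at CT14 and by 1.44 ± 0.10 at CT22, each against CT6. ARNTL (BMAL1) changed by 0.87 ± 0.17 and -1.03 ± 0.17, CRY1 by -1.15 ± 0.09 at CT22, and NR1D2 by 1.59 ± 0.10 at CT22. AANAT was higher than at CT6 by 0.61 ± 0.10 at CT14 and by 1.39 ± 0.10 at CT22. G0S2 had the widest range of the named genes and was higher at CT14 than at CT6 by 3.15 ± 0.24. RASL11A, CRYBA1 and MDGA1 were lower at CT14, where the first 2 had the low means given above, SLC6A9 was higher there, and INHBB and PPEF2 were lower at CT22. GNB3, a phototransduction G protein subunit, was higher at CT14 by 2.00 ± 0.14. In all, 1484 probe sets covering 833 genes changed with time. The values as deposited gave 4194, a fit without a variance trend 377 and all probe sets unfiltered 859. Leaving out the first CT14 dark array gave 755, the first CT22 dark array 761 and the second CT22 dark array 987.

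Lists were tested in the dark only after the data had been seen. Of 66 tests, 17 passed with the preset correlation. With an estimated correlation limma's camera gave 0, with a lowest adjusted p of 0.110 and 8 tests at an unadjusted p under 0.05. Sterol genes lay lower at CT22 than at CT14 (8 lower of 24, or 10 adjusted over the list alone, median -0.31, adjusted p = 2.77e-06, and adjusted p = 0.110 with an estimated correlation). Heat shock genes lay higher at CT22 than at CT14 (10 higher of 29, or 12 adjusted over the list alone, median 0.23, adjusted p = 3.73e-06, and adjusted p = 0.110 with an estimated correlation). Markers of other tissue moved with time too. Choroid plexus markers lay lower at CT22 than at CT14 (median -0.60, adjusted p = 0.00537, and adjusted p = 0.517 with an estimated correlation). Neuron markers lay higher at CT22 than at CT14, 11 of 12 (median 0.42, adjusted p = 2.44e-04, and adjusted p = 0.221 with an estimated correlation), and lower at CT14 than at CT6 (median -0.30, adjusted p = 0.0211, and adjusted p = 0.517 with an estimated correlation). Choroid plexus markers lay higher at CT14 than at CT6 (median 0.48, adjusted p = 0.0132, and adjusted p = 0.58 with an estimated correlation). Fibroblast and meninges markers lay lower than at CT6 at CT14 (median -0.09, adjusted p = 0.0260, and adjusted p = 0.236 with an estimated correlation) and at CT22 (median -0.07, adjusted p = 0.00728, and adjusted p = 0.20 with an estimated correlation). Lymphocyte markers lay lower at CT14 than at CT6 (median -0.48, adjusted p = 0.00277, and adjusted p = 0.663 with an estimated correlation).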

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

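The tests of handling, warming, shared dark arrays, a shift of both CT14 dark arrays, choroid plexus and meninges were chosen only after the result was seen. The tests with the actin ratio were written before their outcome was seen, although the covariate itself was added after the data were seen, and the demand that RNA quality at CT14 hold with each array left out, and the stricter bar for shared dark arrays, were set once the values were known. What marked the results below is a test of the difference in the light response between times, which 311 probe sets passed. Groups of 2 are too small for the test of a stray array within a group, and the effect of each array is given as the counts with it left out.

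The heat shock list rose more at CT22 than at CT6 by a median of 0.39 across 29 genes, with HSPB9 higher by 5.08, BAG3 by 1.98 and HSPA2 by 1.64. With the actin 3-prime to 5-prime ratio as a covariate the median difference was 0.43 (adjusted p = 1.32e-14). That ratio moved this contrast by only 0.04 in the median over all probe sets, so the test could hardly show a part played by RNA quality. The same ratio for GAPDH was lower in light at CT6 (1.16 and 1.19, against 1.26 and 1.25 in the dark). At CT22 it was higher in light (1.25 and 1.31, against 1.23 and 1.22). The GAPDH ratio was not tested as a covariate, so RNA quality stays open here. Handling stress may raise both heat shock and early response genes, and 4 immediate early genes passed and were lower at CT22 (EGR1, BTG2, MAFF, SIK1) while CCN2 was higher, so handling is neither shown nor excluded. Warming by the lamp, which no label records, cannot be told apart from light, because any warming would have reached the same animals in which 19 heat shock genes were raised. A gated response of the gland to light late in the night stays open as a biological hypothesis.

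Probe sets raised at CT14 tended to be low in the CT14 dark arrays, 229 of 264 (86.7%) against 50.5% of all probe sets, and 116 of 122 lowered ones (95.1%) were high there. The dark arrays enter both sides, and the covariance of -0.0920 lay beyond the range of 100 simulations with noise alone (-0.0651 to -0.0526, a difference of -0.0332 from their mean), as it did at CT22 (-0.0545 against a lowest of -0.0449, with 68.6% and 76.0%) but not at CT6 (-0.0522 within -0.0529 to -0.0433, with 65.9% and 60%). As a correlation the excess was slight at CT14, with r = -0.643 against a simulated mean of -0.636. At CT22 r was -0.426 against -0.513 and at CT6 -0.510 against -0.578, weaker than noise alone gave. These raised and lowered sets were chosen with the same dark arrays, so the share over all probe sets is no chance level. The simulated noise was independent between probe sets, and splitting the dark arrays leaves 1 on each side. Part or all of the excess in covariance may therefore come from the shared dark arrays. With the actin ratio as a covariate the median light effect of the raised probe sets went from 0.79 to 0.65, a share of 0.820 that lay above 0.75, but without the second CT14 dark array the share was 0.633, so a part played by RNA quality cannot be told apart from light. The raised probe sets lay 0.32 above the other dark groups in the CT14 light arrays and -0.43 from them in the CT14 dark arrays, so a shift of both CT14 dark arrays, circadian or technical, also stays open.

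Opposite calls at CT14 and CT22 were made for 16 probe sets, where independent lists would give 7.16 over both directions together. ZIC1 and SLCO1C1 enter with more than 1 probe set and the calls share 1 estimate of spread, so 7.16 may be too low. Calls in the same direction were shared by 81 raised and 19 lowered probe sets, against 4.56 and 2.34 for independent lists. Of the 16, 12 were lower at CT14 and higher at CT22, and 4 went the other way. The 16 named DAB2IP, METTL7A, NPTX2, OLIG2, SLC31A1, SLC6A20, SLCO1C1, SMARCC1, TST and ZIC1, and 4 of the 16 have no gene name here. Apart from SLCO1C1 and the list member OLIG2, these genes were chosen after their values were seen. Attached choroid plexus is a candidate source: its markers differed the same way by a median of 0.63 (7 genes, adjusted p = 0.0240, and adjusted p = 0.439 with an estimated correlation), which does not settle it. In the dark these markers also differed, with a median of -0.60 for CT22 minus CT14. Attached meninges had no support from their marker list (adjusted p = 0.812), but a missed threshold does not exclude them. In each of the 12 the CT14 dark mean was the highest of the dark groups, and in each of the 4 the lowest. For SLCO1C1 it was 10.04, against 8.91 at CT6 and 8.12 at CT22. The dark arrays enter both sides, so this order does not settle the cause. A difference of the CT14 dark arrays, circadian or technical, stays open. A light response that turns with time of day also stays open, untested.

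Among the other leading genes for time dependence, the light effect at CT22 exceeded that at CT6 by 1.52 for HERPUD1, and that at CT14 exceeded that at CT6 by 1.43 for SLC4A7. The effect at CT22 minus that at CT14 was -1.38 for BHLHE41, -1.54 for BMP2, -1.55 for CPLX4, -1.21 for MACIR and 2.36 for SLCO1C1. The genes that follow were named for a large light change rather than for time dependence, whose test they also passed. For them the effect at CT22 minus that at CT14 was 2.58 for DIO3, 1.90 for G0S2, 2.35 for GNG11, 2.29 for HSPB8, 2.94 for HSPH1, -1.33 for LSG1, 2.24 for NXNL2, 1.51 for P4HA2, -2.70 for RASL11A, 2.03 for SLC2A12 and 2.74 for TMEM27. EGR1 differed by -0.97 between CT22 and CT6. MEF2D differed by 0.98 and ORAOV1 by -1.32 between CT14 and CT6. For each gene only the largest of its differences between times is given here, so the sizes tend to be too large.

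Of the gene lists, 15 differences passed with the preset correlation, and only that of heat shock between CT22 and CT6 also passed with an estimated correlation. Median differences of CT14 minus CT6 were 0.13 for heat shock, 0.16 for melatonin synthesis and -0.13 for oxidative phosphorylation. For CT22 minus CT6 they were 0.14 for sterol genes, 0.19 for ER chaperones, 0.11 for fibroblast and meninges markers and 0.28 for choroid plexus markers. For CT22 minus CT14 they were 0.25 for heat shock, 0.17 for ER chaperones, -0.20 for clock genes, -0.23 for melatonin synthesis, -0.17 for phototransduction and 0.12 for oxidative phosphorylation.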

How the results depend on the processing

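All alternatives were chosen before the data were examined except the actin ratio as a covariate, which was added after the result was seen. The values as deposited gave 26 probe sets at CT6, 509 at CT22, 404 for the average, 172 for time dependence and 4194 for time of day in the dark. That scale moved the median of all probe sets by 0.12 for light at CT14 and -0.11 at CT22, by 0.11, -0.13 and -0.25 for the differences CT14 minus CT6, CT22 minus CT6 and CT22 minus CT14, and by 0.28 and 0.37 for dark CT22 minus CT6 and CT14, but by 0.01 at CT6 and 0.01 for the average. Arrays centred on their median gave 250 at CT6 (243 higher, 7 lower), with a median of all probe sets of 0.08 there and of -0.10 for CT22 minus CT6. Without a filter the counts were 20 at CT6, 212 at CT14, 426 at CT22, 43 for time dependence and 859 in the dark, with more probe sets tested. The filter at the 60th percentile gave 98 at CT6 and 479 for time dependence. Without a variance trend they were 9, 105 and 162 at the 3 times, 314 for the average, 11 for time dependence and 377 in the dark. A fit of only the 4 arrays of CT6 gave 20. With the actin ratio as a covariate they were 23 at CT14, 246 for the average and 88 for time dependence, and with an estimated inter-gene correlation 7 list tests passed. For the changes in count the cause was not tested.

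Leaving out each array in turn gave 23 to 50 probe sets at CT6, 159 to 416 at CT14, 234 to 832 at CT22, 473 to 634 for the average, 73 to 375 for time dependence, 755 to 1478 in the dark and 13 to 17 list tests. A group left with 1 array was assumed to vary like the others. The CT6 count was 23 without the second CT6 light array. At CT14 it was 224 without the first dark, 221 without the first light and 159 without the second light array. At CT22 it was 234 without the first dark, 337 without the second dark and 307 without the second light array. Time dependence gave 192 without the first CT6 light array, 139 without the first CT14 dark array, 168 and 91 without the first and second CT14 light array, 86 and 116 without the first and second CT22 dark array, and 73 without the second CT22 light array. The dark count was 755 without the first CT14 dark array and 761 and 987 without the first and second CT22 dark array.

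Replicate numbers did not pair the arrays: over 15 pairs of groups the correlation of deviations ran from -0.03 to 0.03. With the number as a block within time the counts were 36, 312 and 722 at the 3 times, 566 for the average, 226 for time dependence and 15 list tests. With the replicate block over all arrays they were 42, 353, 758, 661, 244, 1436 in the dark and 16. Neither block moved a count by over 1.5 times.

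Across 201 results of named genes and list members the alternatives gave 4775 values, 4076 on the same side of the threshold, 699 weaker and 0 of opposite sign. Of the 201 results, 127 lost their call under at least 1 alternative and 74 under none. All had been chosen because they passed. For a light call, leaving out an array of another time changes only its spread and not its size, so the pooled share is a lenient measure. For the 16 called lists 371 of 416 values kept the call, 45 lost it and 0 turned, and 9 of the 16 lost it at least once. Signal near the floor limits low probe sets, since 6.24% of values lay under 1.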

Other observations

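The test of array splits and the look at genes outside the leading lists were chosen only after the result was seen, while the test of cAMP and calcium targets was written before its outcome was seen.

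Single genes of several lists changed at CT22 although their lists did not pass. LDHA, HK1 and ALDOC, enzymes of glycolysis, fell by 0.57, 0.45 and 0.29 on the log2 scale, while 12 of the 22 genes of their list lay higher. The call of ALDOC was lost in 9 of 24 alternatives, among them the values as deposited and arrays centred on their median. Adjusted over the list alone, 4 rose (PKLR, LDHB, PDK1, P4HA1) and 4 fell. PKLR stands here for the listed PKM, which was matched to it through a synonym. Of the ATF4 targets, CHAC1 rose by 1.62 ± 0.29 (SE, limma adjusted p = 0.00907) and the stress regulator ATF4 by 0.56 ± 0.08, and CEBPB fell by 0.79; adjusted over the list alone the counts were the same, 2 up and 1 down. SGK1 and PDK4, glucocorticoid targets, rose by 0.89 ± 0.13 and 0.45 ± 0.11, the call of PDK4 being lost in 15 of 24 alternatives. PTGDS, COL1A1 and COL1A2, genes of the meninges, rose by 0.54 ± 0.07, 0.38 ± 0.10 and 0.40 ± 0.08, with the call of COL1A1 lost in 16 of 24 alternatives, each CT22 array left out included. COL1A1 also rose at CT14, by between 0.72 and 1.17 over the alternatives. At CT22 the myelin gene MBP fell by 0.65 and GFAP, a glial filament gene, by 0.42, while OLIG2 rose by 0.72 ± 0.16 after a fall of 0.88 at CT14. The call of GFAP was lost in 9 of 24 alternatives.

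CXCR4, a chemokine receptor on the lymphocyte list, rose by 0.62 ± 0.10 at CT6 and by 1.42 ± 0.10 at CT14 (limma adjusted p = 6.18e-06), while the list of 20 lymphocyte markers did not pass at either time (adjusted p = 0.961 and 0.284). In the dark CXCR4 was lower at CT14 than at CT6 (-0.58 ± 0.10) and higher at CT22 (0.73 ± 0.10). DIO3 was higher in the dark at CT14 than at CT6 by 1.72 ± 0.28.

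EGR1, BDNF and SIK1 fell with light, and a fall of cAMP or calcium signalling was put forward as a hypothesis. Of 38 other genes known to follow these signals 26 were measured, 5 of them also on the immediate early list. They did not move together in the averaged light response (limma camera adjusted p = 0.961 over 4 light contrasts, median -0.01). PDE4D and ADCYAP1 rose and ETV5 fell. The test gave no sign of such a fall and does not exclude it.

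For the light response averaged over times, 1 of 100 splits drawn from the 108 that exchange arrays within times gave as many probe sets, the real one, with 691. The highest other split, with 4 arrays labelled otherwise, gave 314. The median of the others was 0, and 6 others exceeded 0.1 times the real count. With 100 splits the share cannot fall below 1 of 100, so chance is unlikely for this count but not excluded.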
